A study of Homo sapiens with 22 samples.

How the data were processed

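Gene expression was measured by bulk RNA sequencing in 3 human acute myeloid leukaemia cell lines, EOL1, MV4;11 (written MV411 in the sample titles and from here on) and MOLM13. The 22 libraries fall into 11 groups of 2, each a cell line with 1 treatment. EOL1 received solvent (DMSO), C24 or MS177 at 0.5 µM for 16 h. MV411 and MOLM13 received DMSO, C24, MS177N1 or MS177 at 2.5 µM for 24 h. The labels describe C24 as an EZH2 inhibitor, MS177 as a C24-based degrader of EZH2 that needs the ubiquitin ligase receptor CRBN, and MS177N1 as an analog of MS177 that cannot bind CRBN. Because EOL1 differs from the other lines in dose and time, its values are given beside theirs without a test between lines.

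The submitters named RSEM, DESeq and the human build hg19 as their processing, with no version for either tool. The deposited tables hold RSEM expected counts per gene symbol, not normalized, and these were the input here after rounding to whole numbers. Values within 1e-06 of a whole number made up 16.8% of the EOL1 entries, 35.4% of those of MV411 and 31.5% of those of MOLM13, zeros included, and 16.1%, 32.5% and 28.8% of the entries above 0. The authors' log2 fold changes and the authors' adjusted p-values (p-value columns) are in the same tables, and were used only to count the calls of the deposited table beside those made here. The 22 deposited normalized columns were not used. The tables list 15826 genes for EOL1, 15959 for MV411 and 16251 for MOLM13, and the smallest total over a line's libraries was 10.4, 5 and 5 counts, so genes below some level were left out before deposit. Symbols turned into dates by a spreadsheet (18, 19 and 20 entries) were kept in the tests and are not named. No gene position is given, because the counts were made on hg19 and the annotation used here is on GRCh38. The sources used here do not state whether RNA was selected by poly(A) tail, nor the strand of the libraries.

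Library totals ran from 12.6 to 23.9 M counts. Genes passing the edgeR filter on low counts (filterByExpr) numbered 15171 in EOL1, 13414 in MV411 and 13736 in MOLM13. Each line was fitted once with all its groups by edgeR 4.0.16 (R 4.3.3) with TMM scaling and the robust quasi-likelihood test, and adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. All tests are two-sided. The spread between replicates was small, with a biological coefficient of variation of 1.94% in EOL1, 5.9% in MV411 and 7.86% in MOLM13. Nothing in the sources used here says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. Replicate libraries were not copies of each other, since their differences exceeded counting error by a factor of 1.42 to 17.4 (chi-square per gene). The highest factors were those of MOLM13 MS177N1 (17.4) and MOLM13 C24 (10.6), and their spread enters the tests of every MOLM13 group. For genes of at least 10 CPM (counts per M counts of the scaled library total) the median half-width of the 95% interval of a log2 fold change was 0.11 in EOL1, 0.20 in MV411 and 0.21 in MOLM13. In simulated data with 200 changed genes, the test recovered 89.6%, 70.1% and 67.2% of changes of 0.5 on the log2 scale in the designs of EOL1 C24, MV411 C24 and MOLM13 MS177N1 against DMSO, with 17, 8 and 18 false calls. The changes were placed only in genes of at least 5 CPM under DMSO, in a single simulated data set per design. Recovery among genes of lower counts was not measured.

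Levels are CPM from the scaled library totals, as the mean and the SD over the 2 libraries of a group. Log2 fold changes have a standard error, printed for some genes only, and use a prior count of 0.125, the edgeR default. Log CPM in the list tests uses a prior count of 2. Where the lower group has few counts, the size of a fold change depends on the prior count of 0.125 and is uncertain. Where a group has 0 counts in both libraries the fold is a bound, computed against 3 counts over the group. The bound covers counting error of that group only. It covers neither counting error of the other group, taken at its observed counts, nor the spread between libraries. Gene lists, 37 in all, cover Polycomb subunits and targets, growth and the cell cycle, stress responses, metabolism, the CRBN ligase, blood cell identity, and markers of other cell types. They were tested with camera (limma 3.58.1) against all other genes with a preset correlation of 0.01, for lists with at least 5 tested members, then with a correlation estimated for each list, and with fry. Of the 205 calls camera made over the 15 comparisons, 31 held with an estimated correlation. A list's members were also counted with p-values adjusted over the list alone. Differences in response between MV411 and MOLM13 were tested as interaction terms in a joint fit of both lines (14182 genes).

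The genes named were fixed by a rule. It takes 10 genes in every comparison with DMSO, the 5 largest rises and the 5 largest falls among changed genes with at least 5 CPM in the higher group and no overlap between libraries, and up to 4 members with the smallest p of each list that passed against DMSO. Members that did not pass may serve as examples. This rule, the lists, the tests and most alternatives were written before the data were examined. The alternatives were a replicate block, a fit of only the groups compared, DESeq2 1.42.0, its size factors (RLE) in edgeR, no filter, a mean of at least 100 counts, a minimum fold of 2, leaving out each library, an estimated correlation, fry, and genes past the threshold in either line. Removal of each library's trend on GC content and transcript length (a spline with 5 degrees of freedom, GENCODE 29, matched for 87.5%, 92% and 92% of genes), a fit without mitochondrially encoded genes, and a fit of each compound against its own DMSO library were added after seeing the data. Removing the trend also took out each library's mean deviation over the matched genes, so it rescaled the libraries too. Replicate numbers showed no sign of pairing, since deviations of replicates with equal numbers correlated between -0.084 and 0.057 across genes. Low correlations cannot exclude that libraries of equal number were handled together.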

Results

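The study compared an EZH2 inhibitor (C24), an EZH2 degrader built on it (MS177) and an analog of the degrader that cannot bind CRBN (MS177N1) with solvent in leukaemia cells. EZH2 is the histone methyltransferase of Polycomb repressive complex 2. EOL1 is a line from an eosinophilic leukaemia, and MV411 and MOLM13 are monocytic leukaemia lines. Expression of all genes was read as RNA-seq counts, with 2 libraries in each of 11 groups.

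The EOL1 libraries held 21 and 18.6 M counts for DMSO, 22.5 and 20.6 for C24, and 21.3 and 19.8 for MS177. In MV411 the totals were 14.7 and 14.8 M for DMSO, 16.9 and 14.3 for C24, 16.8 and 15.1 for MS177N1, and 12.6 and 13.3 for MS177. In MOLM13 they were 23.9 and 15.8 M for DMSO, 15.1 and 18.8 for C24, 19.2 and 18.3 for MS177N1, and 17.8 and 20 for MS177.

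What the degrader changed in EOL1 was asked against DMSO at 0.5 µM and 16 h. Genes of the integrated stress response, which cells turn on when amino acids are short or protein synthesis is stalled, rose in MS177-treated EOL1 cells. ASNS, which makes asparagine, reached 219 ± 4.6 CPM (SD, n = 2) against 32.6 ± 0.53, a log2 fold change of 2.75 (SE 0.04, adjusted p = 6.1e-22). CHAC1, which breaks down glutathione, rose by 6.46, the stress hormone gene ADM2 by 7.17, the mTOR brake DDIT4 by 3.41 and the cystine transporter SLC7A11 by 2.92 on the log2 scale. MYC, the growth transcription factor, fell from 760 ± 6.5 to 345 ± 0.35 CPM (-1.14, SE 0.03, adjusted p = 3.9e-19). All 37 tested members of the stress list rose, with a median of 2.22 (camera adjusted p = 6e-23, adjusted p = 0.026 with an estimated correlation).

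Growth and division genes fell in EOL1. MYC targets had 54 members lower, 1 higher and 2 not passing (median -0.68), including TCOF1 at -1.04 and NOLC1 at -0.94. Ribosome biogenesis had 41 lower, 0 higher and 4 not passing (median -0.62). DNA replication had 43 lower, 1 higher and 2 not passing (median -0.75), with RRM2, a ribonucleotide reductase subunit, at -1.15 and UHRF1, which maintains DNA methylation, at -1.29. Mitosis had 46 lower, 0 higher and 1 not passing (median -0.73), with the checkpoint gene MAD2L1 at -1.02 and the cyclin CCNB1 at -0.96. Cholesterol biosynthesis had 23 lower, 1 higher and 2 not passing (median -0.80), with the fatty acid synthase FASN at -1.41 and SQLE at -1.19. As FASN shows, this list is wider than the cholesterol pathway itself. The proteasome had 31 lower, 1 higher and 0 not passing (median -0.35). With an estimated correlation the adjusted p was 0.037 for MYC targets, cholesterol biosynthesis and the proteasome, 0.026 for ribosome biogenesis and mitosis, and 0.035 for DNA replication. Adjusted over the list alone, the counts of these 6 lists and of the stress list were the same.

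Inflammatory and immediate early genes rose in EOL1. The inflammatory and NF-kB list had 22 members higher, 2 lower and 3 not passing (median 1.81), led by the chemokine CXCL8, at 491 ± 14 CPM against 11 ± 0.66, and by the cytokine IL1B at 4.12. Immediate early genes had 19 higher, 1 lower and 4 not passing (median 1.19), with the AP-1 factor JUN at 193 ± 1.5 against 10.2 ± 0.55 CPM and ATF3 at 4.45. The monocyte and macrophage list had 29 higher, 3 lower and 3 not passing (31 and 4 adjusted over the list alone, median 0.78), with the growth factor receptor CSF1R at 3.32 and the Fc receptor FCGR2A at 2.29. These calls kept an adjusted p of 0.037, 0.037 and 0.046 with an estimated correlation. TREM2, a macrophage receptor gene with 0 counts under DMSO, was at least 106-fold higher, ACVRL1 rose by 6.78 and the phosphatase gene DUSP8 by 6.62. Among the largest falls were those of IGLL1 (-4.23, a gene with close copies, so its reads are uncertain), CELSR2 (-3.02), PGM1 and C11orf95 (both -3.0).

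Other calls in EOL1 were lost with an estimated correlation. Higher lists were interferon response (24 up, 4 down, 6 not passing, median 0.80, adjusted p = 0.057 with an estimated correlation), antigen presentation (15, 2 and 5, median 0.41, adjusted p = 0.057), histone genes (13, 0 and 6, median 1.38, adjusted p = 0.092) and p53 targets (19, 6 and 4, median 0.38, adjusted p = 0.17). Lysosome and autophagy (17, 5 and 7, median 0.20, adjusted p = 0.17), cell cycle inhibitors (7, 2 and 2, median 0.30, adjusted p = 0.18) and neutrophil granule genes (10, 5 and 1, median 0.45, adjusted p = 0.18) were also called higher. HLA-DRA, a class II antigen gene, rose by 0.86, the interferon factor IRF7 by 1.40, the histone HIST1H2AC by 4.36, the death gene BBC3 by 2.16, the autophagy gene MAP1LC3B by 1.81 and the granule protease CTSG by 3.32. Lower lists were heat shock (5, 11 and 1, median -0.50, adjusted p = 0.12), ER stress (7, 14 and 3, median -0.26, adjusted p = 0.18), glycolysis and hypoxia (7, 18 and 3, median -0.43, adjusted p = 0.19), oxidative phosphorylation (1, 29 and 7, median -0.20, adjusted p = 0.19) and stemness (1, 4 and 1, median -0.44, adjusted p = 0.19). The chaperones HSPA8 (-1.44) and CALR (-1.29), the glycolytic LDHA (-0.97) and the progenitor factors SOX4 (-1.31) and GATA2 (-1.71) fell, while VEGFA of the hypoxia list rose by 2.32.

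With MS177 in EOL1, 9739 of 15171 genes changed by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 4929 higher and 4810 lower, and 1986 of them by at least 2-fold (1499 higher and 487 lower, 24.5% lower). RNA composition moved in this group too: mitochondrial ribosomal RNAs took 1.21% and 1.18% of counts against 0.446% and 0.438% in DMSO, while the 13 listed mitochondrial genes took 3.51% and 3.14% against 3.24% and 3.20%. RNAs without a poly(A) tail, chosen after their values were seen, were higher in 6 of 6 tested, with RN7SK at 2.65 and RPPH1 at 3.40. The deposited table of the authors calls 3776 higher and 4294 lower. With each library's GC and length trend removed, the split was 3984 higher and 5828 lower (59.4% lower against 49.4%), and medians were 0.18 for cell cycle inhibitors, 0.24 for p53 targets and 0.11 for lysosome and autophagy. Medians of most other lists fell by similar amounts, with MYC targets from -0.68 to -0.80 and PRC1 subunits from 0.02 to -0.12. These moves include the rescaling of the libraries and cannot be credited to the trend alone.

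The same question in MV411, at 2.5 µM and 24 h, gave the following. The integrated stress response rose again, with 38 members higher, 0 lower and 1 not passing (median 1.87, camera adjusted p = 2.2e-23, adjusted p = 0.013 with an estimated correlation). ASNS rose from 12.6 ± 1.3 to 114 ± 10 CPM (SD, n = 2, log2 fold change 3.17, SE 0.11, adjusted p = 1.6e-20). PCK2, a mitochondrial enzyme, rose by 3.23, PHGDH of serine synthesis by 2.95 and the kinase-like TRIB3 by 2.93. NUPR1, a stress-induced chromatin factor, rose by 8.57 to 16 ± 0.38 CPM, HMOX1, the haem oxygenase, by 5.78 to 24.6 ± 3.4 CPM, and SPARC, a matrix glycoprotein, by 6.18 to 78.5 ± 2.2 CPM. FABP3 rose by 6.85 and GPX8 by 6.0. MYC fell from 598 ± 34 to 213 ± 0.66 CPM (-1.49, SE 0.06, adjusted p = 3.8e-19).

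Genes encoded in mitochondria rose in MV411 with MS177, 12 of 13 passing with a median of 1.46 (13 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.11). MT-CO1, a respiratory chain subunit, went from 12200 ± 410 to 32900 ± 1000 CPM and MT-ND1 rose by 1.67. The list's 13 genes took 9.12% and 9.53% of the counts in the MS177 libraries against 3.62% and 3.65% in DMSO, and with both mitochondrial ribosomal RNAs, which are not in the list, the shares were 14.1% and 14.7% against 4.18% and 4.29%. These signs of RNA composition stand beside every other change in this group. Cytosolic ribosomal protein genes had 43 members higher, 0 lower and 13 not passing (median 0.29, 45 higher adjusted over the list alone, adjusted p = 0.32 with an estimated correlation), with RPS24 at 0.54. NRF2 targets, genes of the oxidative stress response, had 13 higher, 2 lower and 2 not passing (median 0.59, adjusted p = 0.16 with an estimated correlation), with SLC7A11 at 5.03 and the ferritin FTH1 at 1.15. SLC7A11 was also named with the integrated stress response in EOL1, so these responses are not fully separate. Immediate early genes had 14 higher, 1 lower and 6 not passing (median 0.83, adjusted p = 0.12), with ATF3 at 3.78 and JUN at 3.13.

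**Figure D1:**
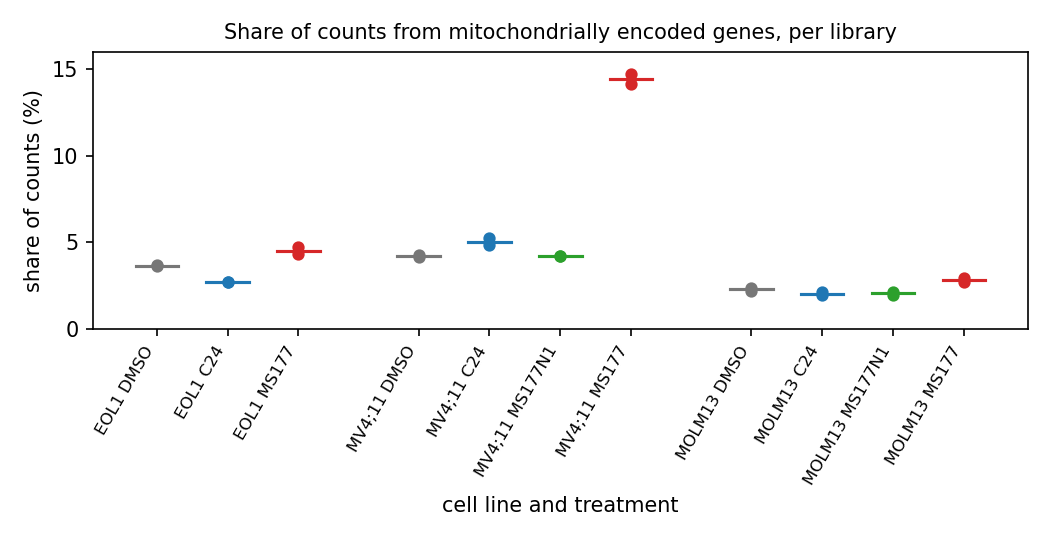
Share of each library's counts taken by 15 genes of the mitochondrial genome, the 13 of the list and both ribosomal RNAs, in percent, for the 11 groups. Points are libraries and lines are group means. The MV411 MS177 libraries lie at 14.1% and 14.7%, and all others between 1.94% and 5.27%.

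Growth genes fell in MV411, although each of these calls was lost with an estimated correlation. MYC targets had 38 lower, 3 higher and 15 not passing (median -0.34, adjusted p = 0.11 with an estimated correlation), with the tRNA synthetase FARSA at -0.99. DNA replication had 32 lower, 2 higher and 12 not passing (median -0.49, adjusted p = 0.10), with POLD1, a replicative polymerase, at -1.67. Mitosis had 30 lower, 4 higher and 13 not passing (median -0.36, adjusted p = 0.12), with AURKB at -1.02. Ribosome biogenesis had 22 lower, 9 higher and 14 not passing (median -0.18, adjusted p = 0.32). Cholesterol biosynthesis had 18 lower, 0 higher and 8 not passing (median -0.61, adjusted p = 0.093), with DHCR7, the last enzyme of the pathway, at -2.69 and FASN at -1.86. Glycolysis and hypoxia had 19 lower, 2 higher and 6 not passing (median -0.65, adjusted p = 0.11), with PFKP at -1.16. Heat shock had 12 lower, 2 higher and 3 not passing (median -0.47, adjusted p = 0.11), with the chaperone HSPA1A at -1.45, while SERPINH1 rose by 1.53. Developmental Polycomb targets had 8 lower, 0 higher and 14 not passing (median -0.53, adjusted p = 0.35, median -0.28 with the GC and length trend removed), with OLIG1 at -1.45, WNT6 at -1.27, WT1 at -1.03 and IRX3 at -0.65.

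IGLL1, with 0 counts under MS177, was at least 54.8-fold lower in MV411, and DDN (-6.88), MMP15 (-5.22), F8A2 (-5.16) and PGM1 (-4.42) fell, where IGLL1 and F8A2 have close copies and are uncertain. Changed genes numbered 6946 of 13414, 3480 higher and 3466 lower, 1752 of them by at least 2-fold (1049 and 703), and the authors' deposited table calls 2586 higher and 3046 lower. Adjusted over the list alone, the counts were 33 lower for DNA replication and 23 lower for ribosome biogenesis, and the other lists kept theirs. With the GC and length trend removed, medians of called lists that moved by over 1.5 times besides the Polycomb targets were ribosomal proteins (0.17) and mitosis (-0.57).

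The same comparison in MOLM13, at the dose and time of MV411, gave fewer changed genes (4035 against 6946) and a smaller stress response. With only the 2 groups compared the counts were closer, 5555 in MOLM13 and 6265 in MV411. Not every list moved less, since cholesterol biosynthesis had a median of -0.81 against -0.61 in MV411. The integrated stress response had 36 members higher, 0 lower and 3 not passing (median 1.05, 38 adjusted over the list alone, camera adjusted p = 5.2e-28, adjusted p = 0.0068 with an estimated correlation). ASNS rose by 1.59 (SE 0.09, adjusted p = 4.9e-09), the folate enzyme ALDH1L2 by 2.01, TRIB3 by 1.47 and NUPR1 by 4.79. The largest rises included genes that are in none of the lists. TREM2 went from 3.72 ± 0.21 to 127 ± 6 CPM (SD, n = 2), ACP5, the phosphatase of osteoclasts and macrophages, from 0.393 ± 0.11 to 38.1 ± 6 CPM, the coagulation factor F13A1 rose by 7.01, the chitinase-like CHI3L2 by 7.45 and the lectin CD209 by 4.87. MYC was 492 ± 4.5 against 596 ± 2.8 CPM (-0.28, SE 0.09, adjusted p = 0.024).

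Cholesterol biosynthesis fell in MOLM13, with 22 members lower, 0 higher and 4 not passing (median -0.81, camera adjusted p = 1.2e-19, adjusted p = 0.0086 with an estimated correlation). INSIG1, which holds back sterol synthesis, fell by 1.84 and DHCR7 by 1.44. All other calls in this comparison were lost with an estimated correlation. DNA replication had 35 lower, 0 higher and 11 not passing (median -0.44, 37 adjusted over the list alone, adjusted p = 0.085), with UHRF1 at -1.08. Glycolysis and hypoxia had 22 lower, 1 higher and 4 not passing (median -0.65, 26 lower adjusted over the list alone, adjusted p = 0.072), with PFKFB4 at -2.27 and BNIP3 at -1.44. MYC targets had 26 lower, 1 higher and 30 not passing (median -0.23, 29 lower adjusted over the list alone, adjusted p = 0.11). Ribosome biogenesis had 14 lower, 1 higher and 30 not passing (median -0.18, adjusted p = 0.25), heat shock 8, 1 and 8 (median -0.29, adjusted p = 0.12), ER stress 11, 2 and 11 (median -0.13, adjusted p = 0.14) and the proteasome 8, 0 and 24 (median -0.12, adjusted p = 0.69). Developmental Polycomb targets had 10 lower, 0 higher and 11 not passing (median -0.46, adjusted p = 0.38), among them NEUROG2, at least 16.9-fold lower. Adjusted over the list alone, 10 heat shock genes and 11 Polycomb targets were lower.

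Several lists were called higher in MOLM13. Immediate early genes had 12 higher, 0 lower and 13 not passing (median 0.45, 14 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation), with JUN at 4.26. Monocyte and macrophage genes had 13 higher, 3 lower and 16 not passing (median 0.27, 15 and 4 adjusted over the list alone, adjusted p = 0.12), with CSF1R at 1.77, and inflammatory genes 11, 4 and 10 (median 0.24, adjusted p = 0.16), with IL1B at 4.34 and CCL4 at 4.59. Histone genes had 7 higher, 0 lower and 8 not passing (median 1.10, adjusted p = 0.12), with H1F0, a linker histone of resting cells, at 3.57. P53 targets had 12 higher, 1 lower and 15 not passing (median 0.21, adjusted p = 0.14), with BBC3 at 1.21, and apoptosis regulators 11, 3 and 12 (median 0.18, adjusted p = 0.16), with BCL2A1, which restrains cell death, at -2.68. Mitochondrially encoded genes had 3 higher, 0 lower and 10 not passing (median 0.27, adjusted p = 0.37), and their share of counts was 2.31% and 2.14% against 1.74% and 1.93%. Ribosomal proteins had 3, 0 and 53 (median 0.19, none adjusted over the list alone, adjusted p = 0.64). Lists of other lineages were lower: eosinophil markers 6, 0 higher and 3 not passing (median -0.66, adjusted p = 0.26), erythroid and megakaryocyte markers 3, 0 and 2 (median -0.56, adjusted p = 0.16), and stemness 2, 0 and 3 (median -0.14, adjusted p = 0.25), with GATA2 at -1.54.

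The largest falls in MOLM13 were NEFM, a neurofilament gene with 0 counts under MS177 and at least 78.3-fold lower, MMP15 (-4.34), CELSR2 (-3.70), LRFN3 (-3.55) and KLC2 (-3.14). Changed genes numbered 4035 of 13736, 1971 higher and 2064 lower, 800 of them by at least 2-fold (481 and 319), and the authors' deposited table calls 1411 higher and 1762 lower. The count was 2329 without DMSO replicate 1, 2372 without DMSO replicate 2, 2612 without MS177 replicate 1 and 2663 without MS177 replicate 2. With the GC and length trend removed, medians were 0.10 for apoptosis regulators, -0.23 for ER stress, 0.15 for inflammatory genes and 0.12 for mitochondrially encoded genes.

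The transcripts of the degrader's own target and of its complex moved little. EZH2 was -0.33 with MS177 in EOL1 (adjusted p = 1.1e-06, 75.2 ± 4.4 against 94.8 ± 4.2 CPM), and did not pass in MV411 (-0.22, adjusted p = 0.071) or MOLM13 (-0.22, adjusted p = 0.084). EED and SUZ12, core partners of EZH2, were -0.21 and -0.24 in EOL1. In MV411 EED was -0.32 (adjusted p = 0.038), and SUZ12 was 0.22 (adjusted p = 0.029) but -0.06 with the GC and length trend removed. In MOLM13 they were -0.18 and -0.09 and did not pass. The related methyltransferase EZH1 was 0.41 in EOL1, 0.30 in MV411 (adjusted p = 0.31) and 0.86 in MOLM13. CRBN was 0.38, 0.68 and 0.55, and IKZF1, a lymphoid factor that other CRBN ligands degrade as a protein, was 0.18, 0.47 and 0.31, all past the threshold. HOXA9, a leukaemia homeobox gene, was 0.06 and 0.21 in EOL1 and MV411, not passing, and 0.31 in MOLM13. Its partner MEIS1 was 0.87, 0.20 (not passing) and 0.44, and the cell cycle inhibitor CDKN1A was 1.27, 0.21 and 0.33. The list of PRC2 subunits did not pass, at medians of -0.23, -0.17 and -0.20 (adjusted p = 0.05, 0.36 and 0.09). With the GC and length trend removed its medians were -0.34, -0.34 and -0.26.

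Several lists passed with MS177 in none of the lines. Medians in EOL1, MV411 and MOLM13 were 0.02, 0.24 and 0.06 for PRC1 subunits, -0.23, -0.04 and -0.02 for the CRBN ligase and degrader neosubstrates, 0.06, 0.20 and 0.07 for the HOXA-MEIS1 programme, and 0.58, 0.10 and 0.11 for ERK pathway output. Lymphoid markers were at -0.19, -0.14 and -0.33 (in MV411 the mean was -1.25 and camera pointed up), and plasma cell markers at 0.01, -0.29 and -0.17. Epithelial and stromal markers were at -0.43 in MV411 and 0.33 in MOLM13, with too few tested in EOL1. Lists that passed in some lines did not in others. In EOL1 these were ribosomal proteins (0.05), apoptosis regulators (0.15), NRF2 targets (0.24), developmental Polycomb targets (0.29), mitochondrially encoded genes (-0.07), eosinophil markers (-0.39) and erythroid markers (-0.11). In MV411 they were p53 targets (0.02), apoptosis regulators (0.21), cell cycle inhibitors (0.21), ER stress (0.00), the proteasome (0.06), lysosome genes (0.04), oxidative phosphorylation (0.00), neutrophil genes (-0.23), monocyte genes (0.12), inflammatory genes (0.12), the interferon response (0.19), antigen presentation (-0.12, mean 0.09), histone genes (0.74), eosinophil markers (-0.38), erythroid markers (-0.40) and stemness (-0.39). In MOLM13 they were mitosis (-0.08), cell cycle inhibitors (0.13), NRF2 targets (0.01), lysosome genes (0.07), oxidative phosphorylation (0.02), neutrophil genes (0.25), the interferon response (0.19) and antigen presentation (-0.00).

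**Figure D2:**
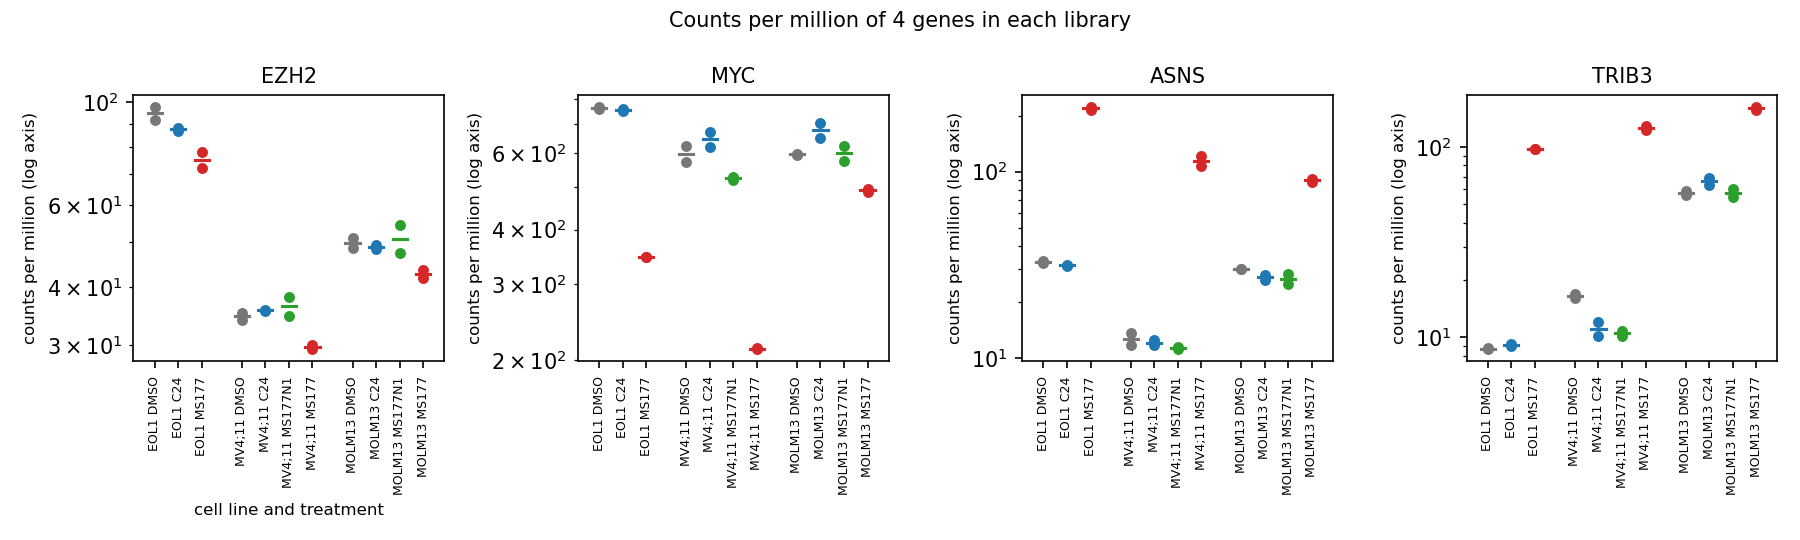
CPM of EZH2, MYC, ASNS and TRIB3 in each library (log axis) by cell line and treatment, with points for libraries and lines for group means. ASNS lies at 219 CPM in EOL1 with MS177 and at 32.6 with DMSO, while EZH2 stays between about 29.8 and 94.8 CPM as group means.

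The inhibitor alone, C24, was compared with DMSO to see what the degrader adds. In EOL1, FOS, an immediate early gene, fell from 35.6 ± 0.071 to 21.4 ± 0.15 CPM (SD, n = 2, -0.73, SE 0.06, adjusted p = 8.3e-07). Of the 13 mitochondrially encoded genes, 4 fell, MT-ND4L by 0.56, MT-ND5 by 0.52, MT-ATP6 by 0.45 and MT-CO1 by 0.44, 0 rose and 9 did not pass (median -0.46, 12 lower adjusted over the list alone, adjusted p = 0.28 with an estimated correlation). The share of these 13 genes was 2.38% and 2.39% in the C24 libraries against 3.24% and 3.20% in DMSO. The ribosomal gene RPS29, which is not in the ribosomal protein list, rose by 0.16 (adjusted p = 0.016), and of the 56 genes in that list 0 rose, 0 fell and 56 did not pass over all genes, with 47 higher adjusted over the list alone (median 0.09, adjusted p = 0.34 with an estimated correlation). DCANP1 and CTD-2515O10.5, the other genes called higher and chosen after their values were seen, were listed at 0 under DMSO and at 1.23 and 2.83, and 1.09 and 0.695 CPM under C24.

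Changed genes in EOL1 numbered 14, 3 higher and 11 lower, with 1574 genes at an unadjusted p under 0.05, and DESeq2 called 71 higher and 52 lower. The authors' deposited table calls 30 higher and 21 lower. The count was 32 without DMSO replicate 2, 206 without MS177 replicate 1 and 216 without MS177 replicate 2. For 9178 of 9192 genes of at least 10 CPM (99.8%) the 95% interval of the C24 effect lay within 1 on the log2 scale. That share was 91.4% for MS177 against DMSO. Antigen presentation (median 0.07), oxidative phosphorylation (0.06), neutrophil genes (0.07, mean -0.08), cholesterol biosynthesis (0.04) and mitosis (-0.04) were called with no member passing, and were lost with an estimated correlation (adjusted p = 0.23, 0.40, 0.34, 0.34 and 0.23). After the GC and length correction the first 3 medians were 0.04, 0.03 and 0.02.

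In MV411, C24 lowered genes of hypoxia and glucose use. DDIT4 fell from 51.9 ± 5 to 23.9 ± 0.64 CPM (SD, n = 2, -1.12, SE 0.09, adjusted p = 3.5e-09), PFKFB4, which drives glycolysis, by 1.03 and NDRG1 by 0.83. DDIT4 was also named with the integrated stress response in EOL1. The glycolysis and hypoxia list had 8 lower, 0 higher and 19 not passing (median -0.16, 11 lower adjusted over the list alone, adjusted p = 0.20 with an estimated correlation). Genes of the cholesterol biosynthesis list rose, with the desaturase SCD at 0.61, SQLE at 0.37 and FDFT1 at 0.34, 6 higher, 0 lower and 20 not passing (median 0.20, 9 higher adjusted over the list alone, adjusted p = 0.20). The monocyte and macrophage list had 6 lower, 0 higher and 22 not passing (median -0.13, adjusted p = 0.23), with CEBPA at -0.37, and the neutrophil list (-0.10) was not called. NRF2 targets had 3 lower, 0 higher and 14 not passing (median -0.14, adjusted p = 0.23), with the ferritins FTH1 at -0.47 and FTL at -0.40. Lysosome genes had 4 lower, 0 higher and 25 not passing (median -0.07, adjusted p = 0.29), with CTSD at -0.31. The integrated stress response had 4 lower, 0 higher and 35 not passing (median -0.08, adjusted p = 0.23), with TRIB3 at -0.58.

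Mitochondrially encoded genes rose under C24 in MV411, 8 higher, 0 lower and 5 not passing (median 0.23, 10 adjusted over the list alone, adjusted p = 0.20), and took 4.57% and 4.20% of counts against 3.62% and 3.65%. Ribosome biogenesis (3 up, 1 down, 41 not passing, median 0.14, adjusted p = 0.20), MYC targets (4, 0 and 52, median 0.09, adjusted p = 0.23), mitosis (1, 0 and 46, median 0.10, adjusted p = 0.23), oxidative phosphorylation (2, 1 and 34, median 0.06, adjusted p = 0.34) and the proteasome (0, 0 and 32, median 0.03, adjusted p = 0.49) were called higher. Immediate early genes were called lower (0, 1 and 20, median -0.15, adjusted p = 0.31). The largest falls outside these lists were PTGER1 (-1.43), SLC6A8 (-1.41), FGR (-1.40) and NCF1 (-1.09, a gene with close copies), and the rises included MSMO1 (0.59), SPRYD7 (0.54) and ATR (0.53). EZH2 was 0.05 and MYC 0.11, neither passing. Adjusted over the list alone, 9 ribosome biogenesis genes, 7 MYC targets and 5 oxidative phosphorylation genes were higher, and 7 monocyte genes, 6 stress response genes, 5 NRF2 targets, 5 lysosome genes and 3 immediate early genes lower.

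Changed genes numbered 619 with C24 in MV411, 76 higher and 543 lower (87.7% lower), 18 of them by at least 2-fold (5 and 13), and the authors' deposited table calls 71 and 543. With the GC and length trend removed the counts were 77 and 146 (65.5% lower), and list medians were -0.10 for glycolysis and hypoxia, -0.07 for NRF2 targets, -0.05 for immediate early genes, -0.04 for the stress response and for lysosome genes, 0.03 for mitosis and for oxidative phosphorylation, 0.00 for the proteasome and 0.15 for mitochondrially encoded genes. The total was 20 without C24 replicate 1, 139 without DMSO replicate 1 and 305 without C24 replicate 2.

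In MOLM13, C24 lowered hypoxia genes too. PFKFB4 fell by 0.87 (SE 0.11, adjusted p = 0.0044), DDIT4 by 0.76, the glucose transporter SLC2A3 by 0.62, NDRG1 by 0.60 and BNIP3L by 0.53, and the glycolysis and hypoxia list had 5 lower, 0 higher and 22 not passing (median -0.22, 10 lower adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). DHRS3 fell by 0.77 and RAB8B by 0.60. The 3 genes called higher were C17orf89 (0.68), CD3EAP (0.55) and XXbac-B461K10.4 (1.09, chosen after its values were seen). MYC targets had 0 higher, 0 lower and 57 not passing over all genes and 10 higher adjusted over the list alone (median 0.14, adjusted p = 0.11), and cholesterol biosynthesis 0, 0 and 26, with 5 higher adjusted over the list alone (median 0.10, adjusted p = 0.11). Ribosome biogenesis (0.09) and heat shock (0.12) were called higher, and monocyte genes (-0.21), cell cycle inhibitors (-0.15), lysosome genes (-0.07) and mitochondrially encoded genes (-0.21) lower, with no member passing and adjusted p = 0.44, 0.30, 0.11, 0.61, 0.21 and 0.61 with an estimated correlation. Adjusted over the list alone, 3 ribosome biogenesis genes were higher and 2 monocyte genes lower. The share of mitochondrially encoded genes was 1.55% and 1.68% against 1.74% and 1.93%.

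Changed genes in MOLM13 with C24 numbered 14, 3 higher and 11 lower, with 1556 at an unadjusted p under 0.05. DESeq2 called 18 higher and 20 lower, and 14 higher and 15 lower are called in the authors' deposited table. With the GC and length trend removed the split was 11 higher and 22 lower. The count was 0 without either DMSO library, 4 without C24 replicate 1, 6 without either MS177 library, 87 without MS177N1 replicate 1 and 102 without MS177N1 replicate 2.

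MS177N1 was compared with DMSO to see what the compound does without CRBN. In MV411, MSMO1 of cholesterol synthesis rose by 0.70 and SCD by 0.55, and NDRG1 fell by 0.42 and the glycolytic PFKL by 0.37. Cholesterol biosynthesis had 5 higher, 1 lower and 20 not passing (median 0.17, 9 higher adjusted over the list alone, adjusted p = 0.29 with an estimated correlation), and glycolysis and hypoxia 0, 3 and 24 (median -0.11, adjusted p = 0.33). Ribosomal proteins had 22 higher, 0 lower and 34 not passing (median 0.11, 28 higher and 3 lower adjusted over the list alone, adjusted p = 0.33), with RPL37 at 0.47. Oxidative phosphorylation had 14 higher, 1 lower and 22 not passing (median 0.18, 20 higher adjusted over the list alone, adjusted p = 0.29), with UQCRQ at 0.41. Developmental Polycomb targets had 5 lower, 0 higher and 17 not passing (median -0.28, adjusted p = 0.33), with the homeobox genes IRX3 at -0.50 and IRX5 at -0.52, and monocyte genes had 6 lower, 0 higher and 22 not passing (median -0.19, adjusted p = 0.29), with SPI1 at -0.30. Lysosome genes were called lower (5 of 29, median -0.06, adjusted p = 0.33), and MYC targets (6 up, 3 down, median 0.08, adjusted p = 0.33), ribosome biogenesis (6 up, 1 down, median 0.11, adjusted p = 0.29), the proteasome (1 up, median 0.08, adjusted p = 0.33) and mitosis (1 up, median 0.06, adjusted p = 0.39) higher.

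The largest falls with MS177N1 in MV411 were SEMA6B (-1.24), LGALS3BP (-1.07), NLRP6 (-1.06), PTGER1 (-0.97) and TMEM189-UBE2V1 (-0.98), and the rises TOPORS-AS1 (0.84), NCK1-AS1 (0.78), SNHG19 (0.74) and HOXA10-AS (0.68). TMEM189-UBE2V1 is a readthrough gene and the antisense genes overlap others, so their reads are uncertain. MYC was -0.19 (adjusted p = 0.03) and EZH2 0.08, not passing. Changed genes numbered 1036, 291 higher and 745 lower (71.9% lower), and the authors' deposited table calls 262 and 655. With the GC and length trend removed the counts were 245 and 247, and list medians were 0.06 for oxidative phosphorylation and for ribosomal proteins, -0.12 for developmental Polycomb targets, -0.02 for lysosome genes, and 0.00 for mitosis and -0.00 for the proteasome. The total was 291 without MS177N1 replicate 1, 407 without DMSO replicate 1 and 638 without MS177N1 replicate 2.

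In MOLM13, MS177N1 changed few genes. CHAC1 fell by 1.14, the interferon-induced IFI6 by 1.01 and SAMD9 by 0.57, and NDRG1 by 0.40. The interferon response had 3 lower, 0 higher and 28 not passing (median -0.23, adjusted p = 0.66 with an estimated correlation), glycolysis and hypoxia 3, 0 and 24 (median -0.16, 7 lower adjusted over the list alone, adjusted p = 0.50), and the integrated stress response 2, 0 and 37 (median -0.10, adjusted p = 0.50). MYC targets had 1 higher, 0 lower and 56 not passing (median 0.11, 10 higher adjusted over the list alone, adjusted p = 0.50), with NOP16 at 0.46. Ribosomal proteins (0.18), oxidative phosphorylation (0.12) and ribosome biogenesis (0.07) were called higher and mitochondrially encoded genes (-0.16) lower with no member passing, each with adjusted p = 0.67 with an estimated correlation. After removal of the GC and length trend these medians were 0.09, 0.07, 0.04 and -0.25, and that of MYC targets 0.04. Markers of epithelial and stromal cells moved with this group, 1 of 10 passing (median 0.52, 2 adjusted over the list alone, adjusted p = 0.67): KRT5, a skin keratin with 0 counts under DMSO, was at 1.87 ± 0.19 CPM (SD, n = 2) and at least 24.5-fold higher. Its partner KRT14, chosen after its values were seen, was at 1.79 and 1.03 CPM against 0 and 0.0637.

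Rises with MS177N1 in MOLM13 included DNHD1 (1.23), SNHG12 (1.21), CPT1B (1.15), LY6G5B (1.07) and LRP5L (0.94), and falls TRIQK (-0.74), TLR9 (-0.61) and C21orf91 (-0.57). Changed genes numbered 134, 57 higher and 77 lower, and the authors' deposited table calls 75 and 157. A fit of only the 2 groups called 15 higher and 0 lower and a fit with a replicate block 6 and 0, so the falls given here did not pass in either, with CHAC1 at adjusted p = 0.085 and 0.061 and IFI6 at 0.058 and 0.064. KRT5 passed in the former (adjusted p = 0.017) and not in the latter (0.061). DESeq2 called 75 higher and 155 lower. The count was 0 without either DMSO library, 39 without MS177N1 replicate 1, 706 without MS177N1 replicate 2, 234 without C24 replicate 1, 221 without C24 replicate 2, 35 without MS177 replicate 1 and 21 without MS177 replicate 2.

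The compounds were next compared with each other at matched dose and time within each line. MS177 against C24 gave the stress response in all 3 lines, with medians of 2.14 in EOL1 (37 of 37 higher), 2.08 in MV411 (38 of 39) and 1.02 in MOLM13 (37 of 39), and adjusted p = 0.029, 0.011 and 0.0094 with an estimated correlation. Cholesterol biosynthesis was lower by medians of -0.87, -0.84 and -0.90 (adjusted p = 0.037, 0.04 and 0.0094 with an estimated correlation). MYC targets were lower by medians of -0.69, -0.44 and -0.38 (adjusted p = 0.037, 0.064 and 0.074). Camera called 12 lists higher and 10 lower in EOL1, 5 and 7 in MV411, and 9 and 11 in MOLM13, of which 10, 2 and 2 held with an estimated correlation. In EOL1 TREML2, at 0 counts under C24, was at least 154-fold higher, ACVRL1 was higher by 8.26 and DUSP8 by 7.96. ACVRL1 and DUSP8 were higher by less against DMSO, so sizes this large may depend on the prior count. In MV411 GPX8 was at least 75.6-fold higher, the small structural RNA RMRP at least 99.1-fold higher, IGLL1 at least 64.3-fold lower, and NUPR1 higher by 8.67. In MOLM13 F13A1 was at least 85.2-fold higher and ACP5 higher by 8.65. Genes that differed numbered 9835 in EOL1 (4966 higher, 4869 lower, and 4060 and 5870 with the GC and length trend removed), 6761 in MV411 (3427 and 3334) and 5241 in MOLM13 (2654 and 2587).

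MS177 against MS177N1, compounds that per the labels differ in CRBN binding, separated as far. The stress list had 38 higher, 0 lower and 1 not passing in both MV411 (median 1.84, adjusted p = 0.0094 with an estimated correlation) and MOLM13 (median 1.09, adjusted p = 0.0083). Cholesterol biosynthesis had 23 of 26 lower in MV411 (median -0.83, adjusted p = 0.035) and 25 of 26 in MOLM13 (median -0.76, adjusted p = 0.011). MYC targets had 45 lower, 1 higher and 10 not passing in MV411 (median -0.41, adjusted p = 0.061) and 39, 2 and 16 in MOLM13 (median -0.38, adjusted p = 0.099). Camera called 5 lists higher and 8 lower in MV411 and 11 and 12 in MOLM13, of which 2 and 2 held with an estimated correlation. MYC itself was -1.30 in MV411 and -0.28 in MOLM13 (adjusted p = 0.017), and EZH2 -0.29 (adjusted p = 0.015) and -0.25 (adjusted p = 0.04). FABP3 was at least 95.3-fold higher and IGLL1 at least 74.8-fold lower in MV411, SPARC was higher by 7.49 and HMOX1 by 7.25, and PRG2 (-3.09) and TK2 (-3.49) were lower. In MOLM13 F13A1 was at least 93.8-fold higher, CD209 higher by 7.45 and SIGLEC6 lower at -2.98. Genes that differed numbered 6499 in MV411 (3271 higher, 3228 lower) and 5258 in MOLM13 (2636 and 2622).

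MS177N1 and C24 were closer to each other than to MS177. In MOLM13 edgeR called 0 genes between them, with 1162 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 3 lower, as did the authors' deposited table. The 95% interval of the difference lay within 1 on the log2 scale for 8829 of 8887 genes of at least 10 CPM (99.3%), and it ran from -0.14 to 0.26 for EZH2 and from -0.36 to 0.01 for MYC. That share was 94.6% even for MS177 against DMSO, so a margin of 1 separates the comparisons little. The count was 545 without MS177N1 replicate 2, 3 without MS177N1 replicate 1, 1 without either C24 library, and 1 and 2 without MS177 replicates 1 and 2. In MV411 175 genes differed, 130 higher and 45 lower with MS177N1, and the authors' deposited table calls 211 and 55. A fit of only these 2 groups called 643, 384 higher and 259 lower. ATF5, a stress transcription factor, was higher by 0.61 (95% interval 0.50 to 0.72, adjusted p = 8.6e-08), DDIT4 by 0.64 (0.45 to 0.83), TBC1D30 by 0.58, THAP3 by 0.56 and the metallothionein MT1X by 0.52. TSC22D2 (-0.68), UBE4A (-0.55), the integrin ITGA4 (-0.53), ZNF503 (-0.51) and IRS2 (-0.49) were lower, and MYC was -0.30 (-0.41 to -0.19, adjusted p = 0.0045).

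Between MS177N1 and C24 in MV411, ribosomal proteins had 16 higher, 0 lower and 40 not passing (median 0.15, 38 adjusted over the list alone, adjusted p = 0.52 with an estimated correlation), oxidative phosphorylation 7, 0 and 30 (median 0.09, adjusted p = 0.59) and mitochondrially encoded genes 6 lower, 0 higher and 7 not passing (median -0.23, adjusted p = 0.52). EZH2 differed by 0.03 (-0.16 to 0.22), and intervals lay within 1 for 8417 of 8445 genes (99.7%). The share was 85.5% for MS177 against DMSO in this line. The 175 became 14 without C24 replicate 1, 58 without C24 replicate 2, 15 without MS177N1 replicate 1, 25 without MS177N1 replicate 2, 312 without MS177 replicate 1 and 310 without MS177 replicate 2. In MOLM13, ribosomal proteins (0.21), oxidative phosphorylation (0.09), glycolysis and hypoxia (0.08), antigen presentation (0.12) and epithelial markers (0.44) were called higher and cholesterol biosynthesis (-0.09) and heat shock (-0.06) lower, with no member passing and adjusted p from 0.35 to 0.77 with an estimated correlation.

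**Figure D3:**
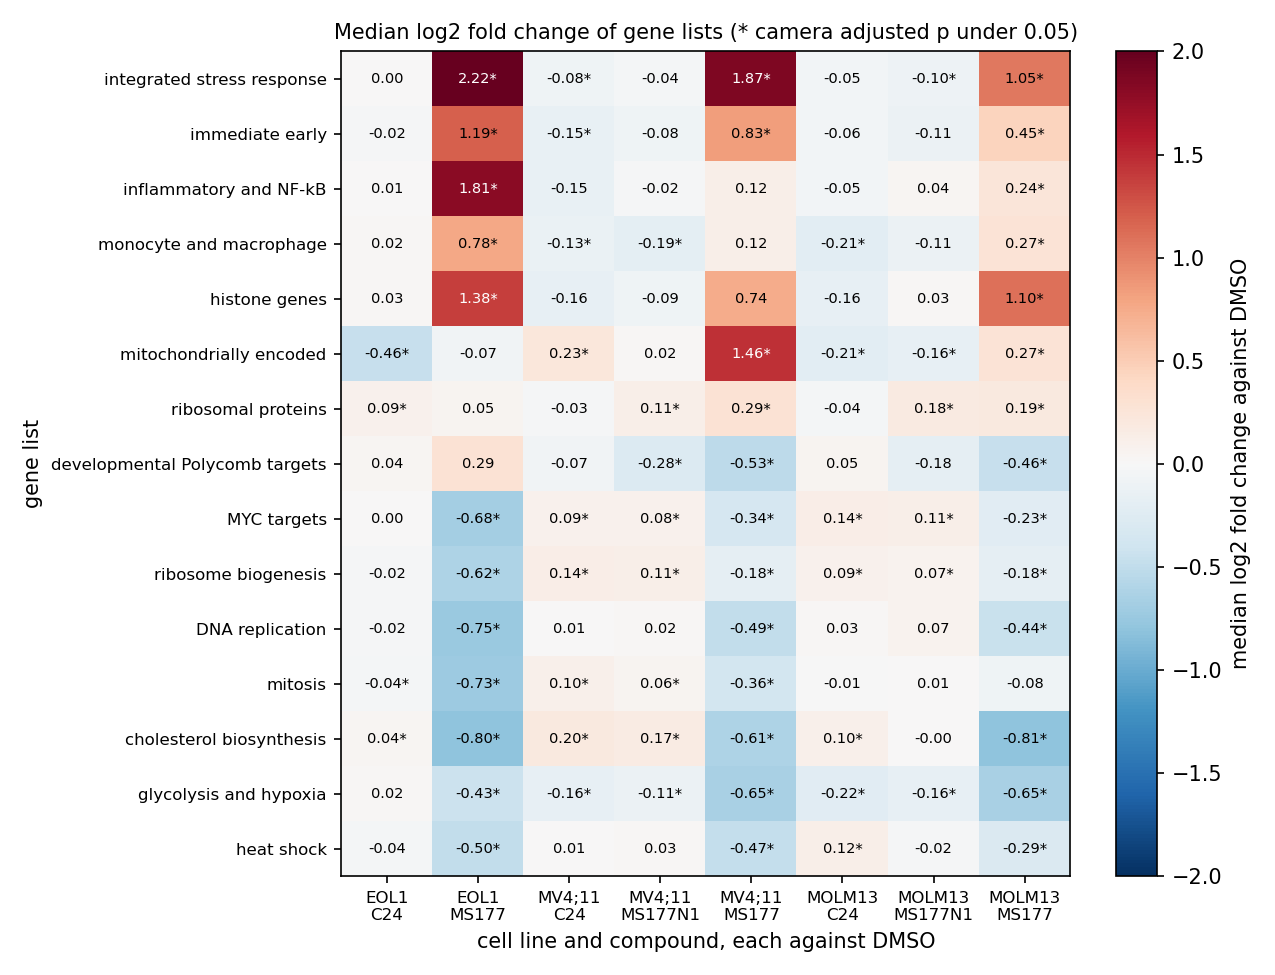
Median log2 fold change of 15 gene lists (vertical) for each compound against DMSO in each line (horizontal), coloured from -2 to 2, with a star where camera passed at the preset correlation. The integrated stress response reads 2.22, 1.87 and 1.05 with MS177 and lies between -0.10 and 0.00 with C24 and MS177N1.

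C24 and MS177N1 share their DMSO libraries, so their fold changes correlate even when nothing changes. Across genes, which are not independent replicates, Pearson r was 0.59 in MV411 and 0.62 in MOLM13, against means of 0.52 and 0.49 in 20 simulations of unchanged groups. The covariance was 0.125 and 0.164 against 0.0676 and 0.07. With each compound set against its own DMSO library, a comparison chosen after the data were seen, r fell to 0.15 and 0.16 in MV411 and to 0.25 and 0.29 in MOLM13 for the 2 ways to assign the libraries. In MV411 354 genes were lower and 26 higher with both compounds, where the numbers called give 30.2 and 1.65 if independent. In MOLM13 7 were lower and 2 higher, against 0.0617 and 0.0124. The simulations with shared controls had mean overlaps of 1 and 0.5, but few genes are called when no group changes. They cannot show how much overlap shared controls bring among the genes called here. With separate DMSO libraries 167 or 79 genes were lower and 8 or 9 higher with both in MV411. In MOLM13 edgeR called 0 genes for either compound against 1 DMSO library, with 1056 and 749 for C24 and 1619 and 1221 for MS177N1 (DMSO replicates 1 and 2) at an unadjusted p under 0.05.

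Across lines, MS177 gave related responses. Of 12183 genes tested in all 3 lines, 1107 rose in all (162 expected by chance) and 1249 fell in all (194 expected), while 951 went opposite ways in some pair. Across genes, Pearson r of the MS177 fold changes was 0.54 between EOL1 and MV411, 0.53 between EOL1 and MOLM13 and 0.55 between MV411 and MOLM13. Of the genes changed in both lines of each pair, 84.1%, 94.2% and 96.9% went the same way. For C24, r was 0.02, 0.01 and -0.01 in the same pairs, and -0.06, 0.12 and 0.45 over genes changed in either line. Of genes changed by C24 in both lines, 2 of 5 went the same way in EOL1 and MV411 and 5 of 5 in MV411 and MOLM13. For MS177N1 r was 0.08 between MV411 and MOLM13 (0.10 over genes changed in either), with 10 of 10 genes changed in both going the same way.

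The responses of MV411 and MOLM13 were tested against each other. MYC fell more in MV411, by a difference of 1.20 (SE 0.10, adjusted p = 4.4e-09), HMOX1 rose more in MV411 (-4.35) and so did NUPR1 (-3.85), while TREM2 (1.57) and F13A1 (3.99) rose more in MOLM13. The EZH2 effect did not differ past the threshold (-0.02, SE 0.13). The integrated stress response rose less in MOLM13, by a median difference of -0.53 (adjusted p = 0.00048 with an estimated correlation). The MS177 effect differed for 2329 of 14182 genes, 1173 higher and 1156 lower in MOLM13, the C24 effect for 58 and the MS177N1 effect for 15. The 2329 became 1357 without MV411 DMSO replicate 1 and 1428 without MOLM13 DMSO replicate 1. The 58 became 4 and 24 without MV411 DMSO replicates 1 and 2, 1 and 14 without those of MV411 C24, 17 without either of MV411 MS177N1, 3 and 1 without those of MOLM13 DMSO, 25 without MOLM13 C24 replicate 1, and 345 and 348 without those of MOLM13 MS177N1. The 15 became 5 and 159 without MV411 DMSO replicates 1 and 2, 6 without either of MV411 C24, 3 and 2 without those of MV411 MS177N1, 6 and 5 without those of MOLM13 DMSO, 43 without either of MOLM13 C24, and 390 without MOLM13 MS177N1 replicate 1.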

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

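Tests chosen only after the result was seen were those of handling, of CRBN binding, of RNA without tails and of the GC and length trend behind the excess of lower genes. The tests of the GC and length trend in the stress response, of scaling, of cytosolic loss and of a single DMSO library were written before their results.

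The results listed here drew attention because MV411 and MOLM13 responded to the same compound by different amounts in a test of the difference itself (MOLM13 minus MV411, log2). The MS177 effect differed for 2329 genes, the C24 effect for 58 and the MS177N1 effect for 15. For MS177 the differences were 1.20 for MYC, -4.35 for HMOX1, -3.85 for NUPR1, 5.16 for DDN, 5.98 for IGLL1, 2.71 for PGM1, 3.99 for F13A1 and 1.57 for TREM2. DDN, IGLL1, NUPR1, HMOX1 and F13A1 had few or no counts in some groups, so their sizes depend on the prior count. For C24 they were -0.79 for MSMO1 and 0.80 for C17orf89, and for MS177N1 -1.10 for MSMO1. The 2329 became 1357 without MV411 DMSO replicate 1 and 1428 without MOLM13 DMSO replicate 1. Leaving out single libraries moved the 58 between 1 (without MV411 C24 replicate 1 or MOLM13 DMSO replicate 2) and 348 (without MOLM13 MS177N1 replicate 2), and the 15 between 2 (without MV411 MS177N1 replicate 2) and 390 (without MOLM13 MS177N1 replicate 1).

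Among gene lists, the MS177 effect differed by a median of -0.53 for the integrated stress response, -0.53 for NRF2 targets, -1.19 for mitochondrially encoded genes, 0.34 for mitosis and -0.18 for ER stress. The C24 effect differed by -0.15 for mitosis and -0.44 for mitochondrially encoded genes, and the MS177N1 effect by -0.16 for cholesterol biosynthesis and -0.16 for mitochondrially encoded genes. With an estimated correlation the stress response held (adjusted p = 0.00048), and the others did not (adjusted p = 0.061 for NRF2 targets, 0.063 for mitochondrially encoded genes, and 0.09 or more for the rest).

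The integrated stress response rose with MS177 in all 3 lines. A GC and length trend as the whole cause is argued against, since the lowest of the 3 medians was 1.11 after the trend was removed. Handling shared by every treated culture is argued against too, since the highest median under C24 or MS177N1 was 0.00. This test was written after the result was seen, and it does not cover handling particular to the MS177 cultures. Binding to CRBN stays open: the lower of the medians of MS177 against MS177N1 was 1.09 in MV411 and MOLM13, but this followed from medians against DMSO that had been seen, EOL1 has no MS177N1 group, and protein was not analysed here.

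Mitochondrially encoded genes were called higher in MV411 with MS177, a list call lost with an estimated correlation (adjusted p = 0.11). Scaling was not decided by its test, where the median was 1.5 with libraries scaled by their nuclear genes. That value restates the higher share of counts that these genes took. It shows a rise relative to nuclear genes, which cannot be told from a fall of nuclear RNA. Loss of cytosolic RNA from damaged cells stays open: the median of 4 nuclear RNAs was 0.06, under the bound of 0.3 set before, but KCNQ1OT1 was 0.93, TUG1 0.43, PVT1 -0.31 and MIAT -4.68, so that bound was wrong for a set that goes both ways, and this condition on the spread was added after the value was seen. MALAT1 and NEAT1 are nuclear RNAs outside these 4, chosen after the data were seen. Both were higher in this group, as such a loss predicts. They were also higher with MS177 in EOL1 and MOLM13, where the mitochondrially encoded list had medians of -0.07 and 0.27. Their rise is thus not particular to the line where that list rose most. RNA without poly(A) tails also stays open, since 7 such RNAs had a median of 3.68 but RN7SL1 (-0.06) and RN7SL2 (-0.45) were not higher. In EOL1 6 of 6 such RNAs tested were higher with MS177, with RN7SK at 2.65, while the mitochondrially encoded list had a median of -0.07. Such RNAs thus rose without the list in that line, at another dose and time, which does not settle MV411. A change in mitochondria themselves was not tested and may also contribute.

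More genes were lower than higher with C24 and MS177N1 in MV411, 87.7% and 71.9% of those changed. A GC and length trend met its test, as the higher share fell to 65.5% and the other to 50.2% when it was removed. The removal also rescaled the libraries, and the test does not separate the trend from that rescaling. Library composition or scaling may thus account for much of the excess. A single DMSO library out of place stays open, since without DMSO replicate 1 the shares were 72.7% and 53.8%, and without DMSO replicate 2 83.6% and 76.9%. A biological cause was not tested.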

How the results depend on the processing

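The GC and length correction and the fit without mitochondrially encoded genes were chosen after seeing the data, as was setting each compound against its own DMSO library, which took the correlation of C24 and MS177N1 effects from 0.59 to 0.15 or 0.16 in MV411 and from 0.62 to 0.25 or 0.29 in MOLM13. Counts of changed genes with MS177 kept to within 1.5 times under every alternative but a 2-fold minimum and leaving out a library, and those of C24 and MS177N1 did not. With a 2-fold minimum the counts were, in EOL1, 1986 (MS177 against DMSO), 2 (C24) and 1996 (MS177 against C24), in MV411 1752, 18 (C24), 25 (MS177N1), 1673 (against C24), 1499 (against MS177N1) and 10 (MS177N1 against C24), and in MOLM13 800, 1, 20, 922 and 884, with 567, 5 and 7 for the differences between lines (MS177, C24, MS177N1), where the threshold itself removes genes. The share of lower genes moved with it, for MS177 against DMSO from 49.4% to 24.5% in EOL1, 49.9% to 40.1% in MV411 and 51.2% to 39.9% in MOLM13, and in MV411 from 87.7% to 72.2% for C24 and from 71.9% to 40% for MS177N1. For all that follows, unless fewer libraries or genes were used by construction, the cause was not tested. With the replicate block EOL1 C24 gave 24, MOLM13 MS177N1 6 and the C24 difference 21. With only the groups compared EOL1 C24 gave 188, MV411 MS177N1 against C24 643, MOLM13 C24 38, MS177N1 15 and MS177N1 against C24 5, and the C24 and MS177N1 differences 308 and 1. DESeq2 gave 123, 268, 38, 230, 4, 267 and 107 for the same results in that order. RLE gave 24 for EOL1 C24, a mean of at least 100 counts 78 there and 112 for the C24 difference, no filter 30 for the MS177N1 difference, and leaving out mitochondrially encoded genes 6 for EOL1 C24. The GC and length correction gave 223 for MV411 C24, 492 for MS177N1, 33 for MOLM13 C24, 5 for MOLM13 MS177N1 against C24, and 10 and 8 for the C24 and MS177N1 differences.

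Of the 205 list calls, 31 held with an estimated correlation, and fry made 290. Correlations of MS177 effects between EOL1 and MV411, EOL1 and MOLM13, and MV411 and MOLM13 were 0.58, 0.58 and 0.63 with only the groups compared, 0.45, 0.43 and 0.35 with DESeq2, 0.43, 0.41 and 0.33 with no filter, 0.61, 0.69 and 0.73 with a mean of at least 100, and 0.57, 0.60 and 0.64 over genes past the threshold in either line. For C24 they were -0.04 and 0.02 (first and last pair) with only the groups compared, -0.08, 0.07 and -0.07 with a mean of at least 100, -0.06, 0.12 and 0.45 over genes past the threshold in either line, and 0.04 in the last pair with the GC correction. For MS177N1 it was 0.20 with a mean of at least 100.

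Leaving out each library in turn, with the lone library of its group assumed to vary like the others, gave 8840 to 9702 genes for EOL1 MS177, 12 to 216 for C24 and 8778 to 9893 for MS177 against C24. In MV411 it gave 5598 to 6700 for MS177, 20 to 879 for C24, 291 to 1411 for MS177N1, 5302 to 6807 against C24, 5067 to 6559 against MS177N1 and 14 to 312 for MS177N1 against C24. In MOLM13 the ranges were 2329 to 4605, 0 to 102, 0 to 706, 3607 to 5727, 3655 to 5425 and 0 to 545. Differences between lines ran from 1357 to 2664 (MS177), 1 to 348 (C24) and 2 to 390 (MS177N1), and list calls from 193 to 211. The correlations ran from 0.44 to 0.53, 0.44 to 0.53 and 0.45 to 0.52 for MS177, -0.02 to 0.08, -0.04 to 0.03 and -0.03 to 0.05 for C24, and -0.01 to 0.11 for MS177N1.

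Counted as reversed were values that changed direction and passed the threshold in the main fit or the alternative. Reversed with the GC and length correction were SUZ12 (-0.06, MV411 MS177), FASN (0.04, MV411 MS177N1), the proteasome (-0.15) and oxidative phosphorylation (-0.18) with MS177 in MV411, and mitochondrially encoded genes with MS177N1 in MV411 (-0.18). Medians of other lists changed sign without being counted. With MS177 these included the interferon response in MV411 (0.19 to -0.04) and PRC1 subunits in EOL1 (0.02 to -0.12). Reversed in direction by fry were lymphoid markers in EOL1 MS177 (-0.19, and -0.02 against C24) and plasma cell markers in MOLM13 MS177 against C24 (-0.15). Without a single library of MOLM13, ribosomal proteins with C24 (-0.17 to 0.08, the highest without C24 replicate 1), oxidative phosphorylation in MS177N1 against C24 (0.00 to 0.21, the lowest without MS177N1 replicate 1) and ribosomal proteins in MS177 against MS177N1 (-0.14 to 0.18, the lowest without MS177N1 replicate 2) reversed. Of 610 values of named genes, 606 were the same with RLE, 601 with no filter, 568 with only the groups compared, 577 with the block and 536 with the GC correction, and DESeq2 kept 492 of 535. Of 552 list values, 547 were the same with RLE, 539 with no filter and 482 with the GC correction. Pseudocount alternatives were not run, since the data are counts, and DESeq2 has no list test. Depth was not varied. At the depth, replicates and spread of MV411 C24, a simulation found 70.1% of changes of 0.5 and 95.5% of changes of 1 among genes of at least 5 CPM under DMSO.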

Other observations

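The genes in this part were chosen after the data were seen, except the nuclear RNAs KCNQ1OT1, TUG1, MIAT and PVT1, and no explanation is offered. Some nuclear and structural RNAs are given here for MS177, and they did not move as a class. MALAT1, a nuclear RNA, was 0.97 in EOL1, 3.84 in MV411 and 1.02 in MOLM13 (log2, against DMSO), and NEAT1 1.74, 1.04 and 0.66. The mitochondrial ribosomal RNAs MT-RNR1 (2.15, 3.70 and 0.62) and MT-RNR2 (1.19, 3.15 and 0.31) went in the same direction. Of RNAs without a poly(A) tail, 6 of 6 tested passed in EOL1: RN7SK (2.65), RPPH1 (3.40), SNORD3A (2.58), SCARNA2 (1.69), RN7SL1 (0.42) and RN7SL2 (0.56). In MV411 RN7SK (3.68), RPPH1 (4.32), RMRP (5.23), SNORD3A (3.94) and SCARNA2 (2.76) passed, and RN7SL1 (-0.06) and RN7SL2 (-0.45) did not. In MOLM13 none of 6 passed by edgeR: RN7SK (0.71), SNORD3A (1.35), SCARNA2 (-0.93, adjusted p = 0.37), RN7SL1 (-0.06), RN7SL2 (-0.08) and RMRP (6.04, SE 3.99). Of the nuclear RNAs in MV411, KCNQ1OT1 (0.93) and TUG1 (0.43) rose, MIAT (-4.68) fell and PVT1 (-0.31) did not pass.

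KRT5 read 2 and 1.74 CPM in the MOLM13 MS177N1 libraries and 0 in every other MOLM13 library.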
